A study of Homo sapiens with 12 samples.

How the data were processed

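RNA from 12 cultures was measured on 1-colour Illumina bead arrays, in 4 groups of 3 biological replicates per the labels. The groups were HCC827-Del and HCC827-Del-TM, each with DMSO or with decitabine (2.5 µM) plus vorinostat (1 µM) for 72 h. Per the labels' protocols, total RNA was purified with Trizol and spin columns and converted to biotinylated cRNA with a MessageAmp kit. The p-values rest on the spread between these cultures, 3 per group.

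Per the file headers and the values, the authors deposited probe signal intensities that were neither background-subtracted nor normalized between arrays. Beside each signal, the deposited table holds a detection p-value, computed by the authors from control probes that were not used here. The authors also deposited log2 values, which are quantile-normalized between arrays and not background-subtracted, as the values show (all 12 sorted columns are identical, with a median of 6.64 and a lowest value of 6.25). The software behind these steps is not given in the sources used here. Gene symbols came from a table that pairs probes with genes: of 47323 probes, 30113 had 1 symbol, 8 had several and 17202 had none. Probes without 1 symbol were not analysed here. The symbols covered 20046 genes.

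Unless the authors' values are named, values in the text were computed from the deposited signals, in R 4.3.3 with limma 3.58.1 and statmod 1.5.0. Background was corrected with limma's nec (normal-exponential model, noise inferred from the detection p-values, offset 16), followed by quantile normalization and log2. A probe was kept when its detection p was under 0.01 on at least 3 of the 12 arrays, which left 19833 probes, 15667 of them with 1 gene symbol. For each of 11808 genes, the kept probe with the highest mean was tested. Of 3087 genes with several kept probes, 36, 28, 13, 55 and 20 had probes past the threshold in both directions in the 5 comparisons, in the order of the report. Kept probes of a gene could also differ in size, and values are those of the probe tested unless another is named. The computed values correlated with the authors' log2 values at r = 0.981 on each array. Median signals ran from 95.4 to 104 per array, and the SD of the log2 difference between replicates over genes from 0.18 to 0.206. The median standard error of a log2 fold change was 0.095 (0.13 for the difference of treatment effects).

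A linear model with 1 coefficient per group was fitted with limma's lmFit and eBayes to all 12 arrays, and group means were compared in 5 contrasts. P-values were two-sided and adjusted over all genes tested by Benjamini-Hochberg, with a threshold of 0.05. Where no probe of a gene was detected in 1 of the groups, the fold is given as a lower bound ("at least"), the mean of the bright group over the mean of the lowest detected signal on each array of the other group. Lists of genes were tested with limma's camera at a preset inter-gene correlation of 0.01, again with a correlation estimated per list, and with fry. Camera compares a list with the other genes, while fry tests whether a list's genes move on balance in 1 direction and compares it with no other genes. Camera's p-values were adjusted over the lists within a comparison. The 27 lists held 747 symbols, of which 696 had a probe and 530 were tested. They covered silenced and germline genes, immune, proliferation, signalling, stress and metabolic genes, cell lineages, and markers of other cell types.

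The tests, lists, thresholds and alternatives were fixed before the data were examined. So was the rule for naming genes. The rule took the 6 highest and 6 lowest log2 fold changes among called genes detected on all arrays of both groups (5 and 5 for the difference of treatment effects), and up to 6 genes per direction with the largest bound. It further took up to 4 members per list by absolute log2 fold change, and genes tied to the design or the drugs, among them EGFR, TET1, TET2, TET3, DNMT1, DNMT3A, DNMT3B, UHRF1, CDKN1A, CEBPA and HDAC1. A named gene may appear in a comparison other than the one that selected it. Chosen after the values were seen were 4 further lists (inflammatory, myeloid, squamous and barrier, and decitabine uptake genes) 2 alternatives (1 gene per cancer-testis family, and leave-one-out list tests with the full set's probes) and the test on CDKN1A in the closing section. XIST and Y-linked genes were left out.

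Alternatives fixed in advance were median scaling, cyclic loess, no background correction, the authors' values, 3 other detection filters, other ways to use the probes of a gene, other variance models and array weights, only the 2 groups compared, other thresholds, the replicate number as a block, and leaving out each array in turn. The chip as a block was not run. On simulated data with 200 changed genes among 11808, changes of 2-fold were recovered for 98%, 94%, 96%, 98% and 86% of genes in the 5 comparisons, in the order of the report, and changes of 1.5-fold for 82%, 86%, 84%, 84% and 46%. Between 6 and 11 of 11578 unchanged genes were called. The simulation changed far fewer genes than were called in the data, as many up as down, with independent noise and no detection limit. Its rates therefore need not hold for the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.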

Results

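Expression was profiled on 12 Illumina bead arrays, each hybridised with RNA from HCC827-Del or HCC827-Del-TM cells. HCC827 is a human lung adenocarcinoma line with a mutant, activated EGFR. Per the labels, HCC827-Del carries a deletion in EGFR, and HCC827-Del-TM carries the deletion with a further substitution in the same gene. Each line was cultured for 72 h with DMSO (control) or with 2.5 µM decitabine, an inhibitor of DNA methyltransferases, plus 1 µM vorinostat, an inhibitor of histone deacetylases. No group received a single drug, so no change below can be assigned to either drug. Each of the 4 groups held 3 biological replicates. The number of arrays limits the precision of every value below.

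Of 47323 probes per array, 18617 to 19671 were detected in treated HCC827-Del and 17270 to 18055 in its control. In HCC827-Del-TM, 16251 to 17642 probes were detected after treatment and 16527 to 17545 in the control. Log2 intensities correlated across genes at r = 0.995 to 0.996 between replicates and at 0.931 to 0.972 between groups. After filtering, 11808 genes were tested. EGFR mRNA was abundant on all 12 arrays. Its log2 difference was -0.01 for treatment in HCC827-Del (SE 0.0656, adjusted p = 0.914), 0.09 for treatment in HCC827-Del-TM (adjusted p = 0.27) and -0.01 between the control lines (adjusted p = 0.924). With the mean over its 4 kept probes in place of the brightest, EGFR rose by 0.34 after treatment in HCC827-Del (adjusted p = 0.00036), was 0.24 higher in untreated HCC827-Del-TM (adjusted p = 0.00683) and at -0.16 in treated HCC827-Del-TM against treated HCC827-Del (adjusted p = 0.0363), which no other alternative gave. TET1, the demethylase in the series' title, had 3 probes that were detected on at most 1 of the 12 arrays, so it was not tested. TET2 (1 probe) and DNMT3A (3 probes) were detected on 0 arrays, and TET3 was not analysed here.

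**Figure D1:**
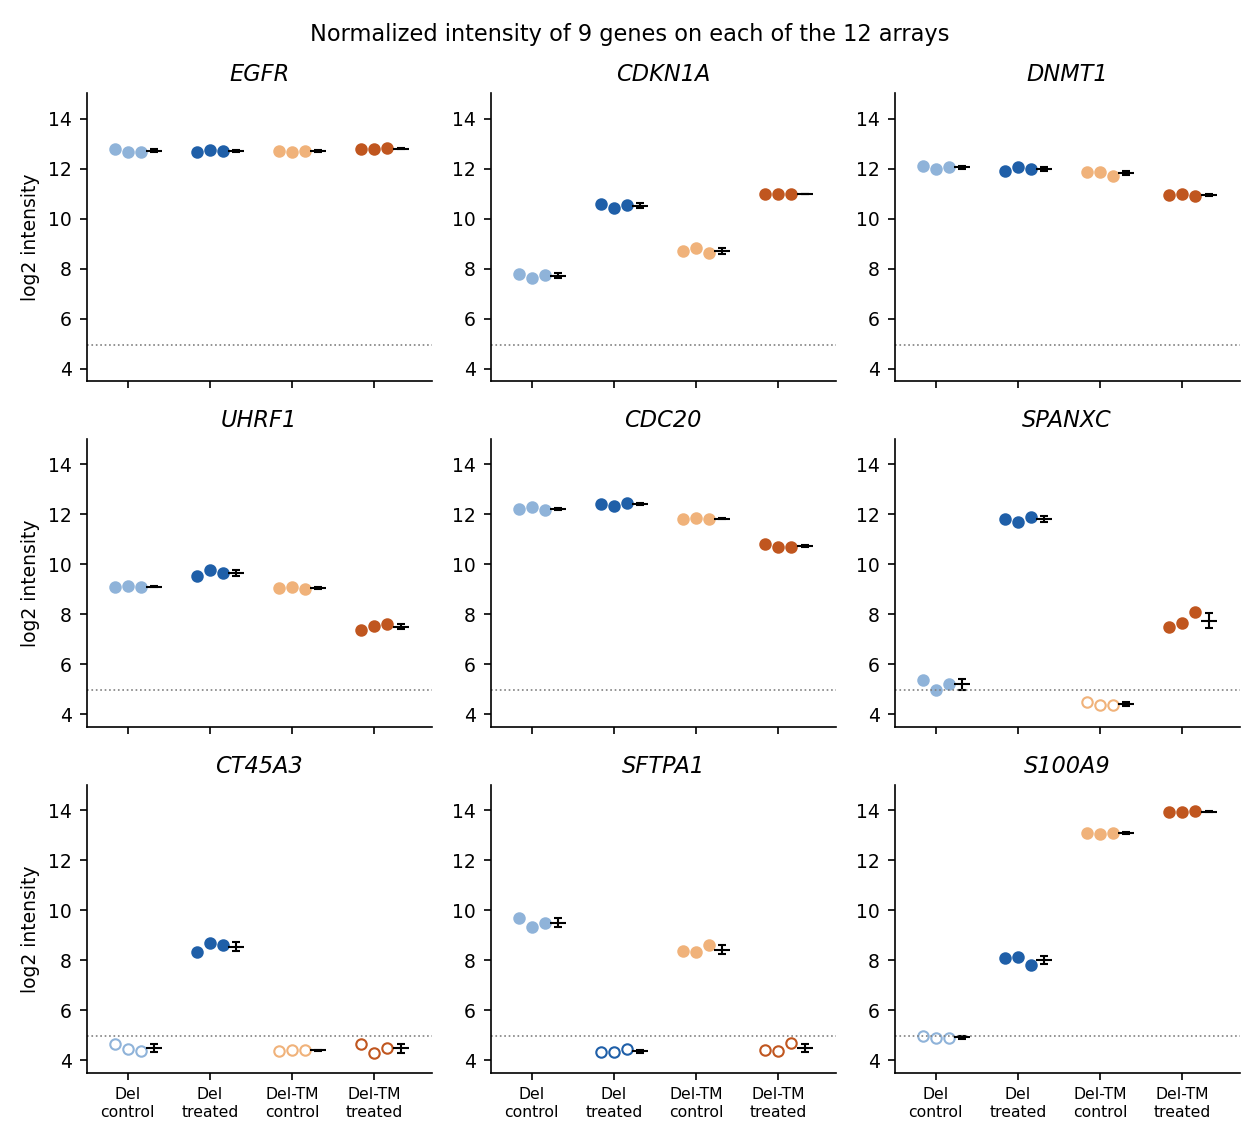
Normalized log2 intensity (y axis) of 9 genes on each array, by group (x axis), with 3 replicates per group as circles (open where the probe was not detected), the mean ± SD beside them and the average detection limit as a dotted line. EGFR was detected on all arrays, CDKN1A was higher after treatment in both lines, CT45A3 was detected in treated HCC827-Del alone, SFTPA1 was lost after treatment in both lines, and DNMT1, UHRF1 and CDC20 were lowest in treated HCC827-Del-TM.

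The first comparison asked which transcripts changed in HCC827-Del after decitabine with vorinostat. Cancer-testis antigens, which are normally restricted to germ cells and are often silenced by promoter methylation elsewhere, rose most. SPANXA2, SPANXB1 and SPANXC, X-linked genes for sperm proteins, rose by log2 fold changes of 6.95 (SE 0.0983), 6.79 (SE 0.149) and 6.61 (SE 0.139; n = 3 per group). SPANXD and SPANXA1 went from undetected in the control to at least 50.4-fold and 50.2-fold higher signal. The X-linked, testis-expressed genes VCX, VCX3B and VCX3A likewise rose at least 34.9-fold, 34.7-fold and 34.2-fold. The other kept probe of VCX3A gave a log2 fold change of 0.984 (adjusted p = 4.1e-05). In the opposite direction, SFTPA1 and SFTPB, surfactant protein genes of alveolar type II cells, became undetectable, at least 26.1-fold and 3.14-fold lower.

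Of 23 measured cancer-testis antigens, 22 rose and 0 fell (camera adjusted p = 3.78e-17). Here and below, counts of list members are of those past the threshold, and the counts adjusted over the list alone were the same unless given. Most of the 23 passed the detection filter through treated HCC827-Del, which favours a rise. Without the filter, 23 of all 37 members with a probe rose and 1 fell (median 0.88, adjusted p = 1.5e-15). CT45A3 and MAGEB2 rose from undetected to at least 11.9-fold and 17.3-fold higher levels. The other kept probe of MAGEB2 gave a log2 fold change of 1.42 (adjusted p = 3.8e-06). Over the 22 members with a fold or a bound, the median log2 fold change was 1.11 with members undetected in the control at their bound. Probes of the SPANX, VCX, MAGEA, GAGE, CT45 and SSX families can bind near-identical copies, so the single member behind each signal is uncertain. Of 15 germline and meiosis genes, 12 rose and 2 fell (adjusted p = 4.11e-05), and without the filter 17 of 35 rose and 2 fell (adjusted p = 2.55e-05). Among them, MAEL and PIWIL2, which act in the piRNA pathway, rose at least 2.6-fold and 1.77-fold, and BRDT, a testis-specific bromodomain gene, at least 1.63-fold. H2AB1, a testis histone variant gene, and TKTL1, a transketolase-like gene, rose at least 14.9-fold and 13.7-fold.

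Genes of other lineages were also higher in treated HCC827-Del. Endothelial and smooth muscle markers rose from undetected, with VWF at least 2.74-fold and desmin (DES) at least 1.73-fold higher. The 5 measured members all rose, but passed the filter through treated HCC827-Del alone; without the filter, 6 of 13 rose and 0 fell (adjusted p = 0.000737). Of 15 mesenchymal genes, 11 rose and 3 fell (adjusted p = 0.00189), including collagen COL6A3 at least 6.4-fold and S100A4 (2.32, SE 0.118). Without the filter, 9 of 30 mesenchymal genes rose and 3 fell (median 0.07, adjusted p = 0.00846). Neuronal genes gave 10 rises and 5 falls of 15 (adjusted p = 0.0331, and adjusted p = 0.0885 with an estimated correlation), among them STMN3 (1.70, SE 0.102) and VGF (1.32, SE 0.081). Without the filter, 10 of 37 neuronal genes rose and 4 fell (median 0.06, adjusted p = 0.0398, and 0.0732 with an estimated correlation). Of 8 metallothionein genes, which bind zinc and copper, 6 rose and 0 fell (adjusted p = 0.00189), with MT1E at 2.98 (SE 0.127). Of 5 blood cell markers, 2 rose and 1 fell (3 and 1 adjusted over the list alone), and the T cell gene CD3D rose at least 5.8-fold from undetected, but the list did not pass (adjusted p = 0.225).

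Lung epithelial identity genes fell as a group, with 12 of 16 lower and 3 higher (median -1.10, adjusted p = 0.000333). Without the filter, 12 of 26 were lower and 3 higher (median -0.0976, adjusted p = 0.000838). NKX2-1, the lineage transcription factor of distal lung, fell by 1.43, CEACAM5 by 1.99 and SPDEF by 1.78. KRT4, a keratin of stratified epithelium, fell by 4.38 (SE 0.1, adjusted p = 5.48e-13), the lowest value among genes detected in both groups. GTF2IRD2B fell by 2.61, SLC16A9 by 2.43, HGD by 2.42, TMEM105 by 2.39 and the imprinted gene PEG10 by 2.20. The other kept probe of HGD gave -0.26 (adjusted p = 0.14). Mitotic genes fell slightly as a group, with 11 of 33 lower and 1 higher (median -0.18, adjusted p = 0.0383, and adjusted p = 0.1 with an estimated correlation). CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21, rose by 2.79 (SE 0.0789, adjusted p = 4.04e-12), while 9 of 22 p53 targets rose and 3 fell (adjusted p = 0.356). Outside the lists, the beta-defensin gene DEFB103A (4.32, SE 0.0885), the tubulin gene TUBB2B (4.29, SE 0.085) and FAM25A (3.89, SE 0.117) rose strongly, and SBSN, a skin barrier gene, rose at least 26.4-fold.

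Of 27 tumour suppressors reported as methylated in lung cancer, 7 rose and 8 fell in HCC827-Del (7 and 9 adjusted over the list alone), and the list did not pass (adjusted p = 0.668). SEMA3B fell by 1.32 and MGMT, a DNA repair gene, by 1.14. CEBPA, a myeloid and lung transcription factor gene, rose by 0.38 (SE 0.107, adjusted p = 0.00825). The maintenance methyltransferase gene DNMT1 gave -0.06 (adjusted p = 0.519), whereas its partner UHRF1 rose by 0.55 and the de novo enzyme gene DNMT3B by 0.73. The DNA methylation machinery list had 4 of 14 members higher and 3 lower (adjusted p = 0.644). HDAC1, a target of vorinostat, gave 0.13 (adjusted p = 0.147), and the deacetylase and acetyltransferase list had 1 of 24 members higher and 10 lower (0 and 10 adjusted over the list alone, adjusted p = 0.098, and 0.0336 without the detection filter). With an estimated correlation, the list did not pass without the filter either (adjusted p = 0.213). The pro-apoptotic gene BMF fell by 1.68, while 6 of 27 apoptosis regulators rose and 4 fell (5 and 4 adjusted over the list alone, adjusted p = 0.527).

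In all, 6059 of 11808 genes passed limma's test at an adjusted p under 0.05, with 2933 higher and 3126 lower, and 535 genes went from undetected to detected on all 3 arrays against 35 the other way. A log2 fold change of at least 1 was reached by 768 genes, 560 higher and 208 lower. With median scaling of the arrays in place of quantile normalization, 61.2% of the called genes were higher in place of 48.4%. Of 27 lists, 8 passed, but 2, 4 and 3 passed without replicate 1, 2 or 3 of treated HCC827-Del, because genes detected in that group alone then left the filter of 3 arrays and the endothelial list fell below 3 measured genes. In these 3 cases the germline (adjusted p = 0.47, 0.595 and 0.415), neuronal (0.06, 0.0556 and 0.0696) and mitotic calls (0.06, 0.0824 and 0.106) ended, as did metallothioneins without replicate 1 or 3 (0.06 and 0.0696), mesenchymal genes without replicate 1 (0.06) and mitotic genes without control replicate 1 (0.0584). Among the 9203 genes detected on all 12 arrays, which include 0 cancer-testis antigens and 4 germline genes, 0 of 25 lists passed camera, while 6 had an unadjusted p under 0.05 and 20 passed limma's fry.

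The second comparison asked the same of HCC827-Del-TM. Mitotic and DNA replication genes fell, and MHC class II genes rose. Among genes detected on all arrays of both groups, the largest rises were in single genes. Outside that group, SPANXB1 rose by 4.04, as given below. The serpins SERPINB4 and SERPINB3, first known as squamous carcinoma antigens, rose by 4.16 (SE 0.0925) and 3.48 (SE 0.0908). The antimicrobial genes RNASE7 and S100A8 rose by 3.88 (SE 0.0942) and 3.67 (SE 0.097), and CAMP, the cathelicidin gene, rose at least 4.81-fold from undetected. TCN1 (3.64) and the mucin-like gene FCGBP (3.59) also rose.

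All 33 measured mitotic genes fell (median -1.12, adjusted p = 4.06e-21), as did 30 of 33 DNA replication genes (32 adjusted over the list alone, median -1.03, adjusted p = 1.48e-17). The kinesin KIF20A fell by 1.69, the kinase AURKB by 1.58, the transcription factor FOXM1 by 1.51 and cyclin A (CCNA2) by 1.46. RRM2, a ribonucleotide reductase subunit, fell by 1.79 (SE 0.137, adjusted p = 1.84e-07), thymidylate synthase (TYMS) by 1.72, the helicase gene MCM4 by 1.71 and CDC45 by 1.68. MYB fell by 1.87, DPP7 by 1.87, CHIA by 1.78 and EMP3 by 1.73. UHRF1 fell by 1.55 (SE 0.08) and DNMT1 by 0.88 (SE 0.0747), while DNMT3B gave 0.08 (adjusted p = 0.388). CDKN1A rose by 2.27 (SE 0.0789, adjusted p = 1.06e-10).

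Immune-related lists rose. Of 35 interferon-stimulated genes, 24 rose and 1 fell (25 and 2 adjusted over the list alone, adjusted p = 2.19e-06, and adjusted p = 0.182 with an estimated correlation), among them EPSTI1 (1.60) and OAS1 (1.08). Of 8 MHC class II genes, 7 rose and 0 fell (median 1.08, adjusted p = 5.64e-05), with HLA-DRB1 at 1.48 (SE 0.111) and HLA-DRA at 1.22 (SE 0.0909). MHC class I and antigen processing had 10 of 19 members higher and 3 lower (12 and 4 adjusted over the list alone, adjusted p = 0.0157, and adjusted p = 0.0626 with an estimated correlation), including HLA-F (0.85).

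Histone genes with polyadenylated transcripts rose in 8 of 14 cases and fell in 2 (8 and 3 adjusted over the list alone, adjusted p = 0.00333, and adjusted p = 0.0612 with an estimated correlation), led by H1-2 (2.34) and H4C8 (2.27). Of 23 ER stress and amino acid response genes, 14 rose and 2 fell (14 and 3 adjusted over the list alone, adjusted p = 0.00259, and adjusted p = 0.112 with an estimated correlation), including the stress transcription factors ATF3 (1.66) and DDIT3 (1.41). Of 15 mesenchymal genes, 6 rose and 1 fell (adjusted p = 0.0157, and adjusted p = 0.0626 with an estimated correlation), with vimentin (VIM) at 2.14. Apoptosis regulators gave 10 rises and 3 falls of 27 (adjusted p = 0.0469, and adjusted p = 0.112 with an estimated correlation), including the inflammatory caspases CASP1 (1.52) and CASP4 (1.00). Of 19 cholesterol synthesis genes, 11 fell and 1 rose (11 and 2 adjusted over the list alone, adjusted p = 0.0487, and adjusted p = 0.112 with an estimated correlation), with the sterol sensor INSIG1 at -1.50. The other kept probe of INSIG1 gave -0.141 (adjusted p = 0.2).

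Lung lineage genes fell here too, 12 of 16 lower and 2 higher (adjusted p = 5.64e-05). SFTPA1, SFTPB and KRT4 became undetectable, at least 10.4-fold, 8.17-fold and 6.92-fold lower, and MUC1 fell by 1.49. FBP1, a gluconeogenic enzyme, was lost at least 3.44-fold and SLC16A9 at least 2.65-fold. Cancer-testis antigens rose in 6 of 23 cases and fell in 0 (5 and 0 adjusted over the list alone, adjusted p = 0.0157, and adjusted p = 0.0626 with an estimated correlation). The call ended with 1 gene per family (adjusted p = 0.122), since SPANXB1 (4.04), SPANXC (at least 6.51-fold), SPANXA1 (at least 4.29-fold) and SPANXD (at least 3.22-fold) make up most of the 6. SPANXA2, which the list did not hold, rose at least 17.9-fold, and MAGEB2 rose by 2.02. In all, 18 of the 23 antigens were detected in neither group. The tumour suppressor list had 8 of 27 members higher and 4 lower (adjusted p = 0.275), with CDKN2B, which encodes the kinase inhibitor p15, at 1.47, and CEBPA was lost at least 1.21-fold.

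HCC827-Del-TM had 5413 genes past the threshold, 2562 higher and 2851 lower, of which 591 reached a log2 fold change of at least 1 (353 higher and 238 lower). Of 27 lists, 12 passed camera. The apoptosis call ended with the replicate block (adjusted p = 0.0549), among genes detected on all 12 arrays (0.0593), with a detection p under 0.05 (0.0522) and without replicate 2 or 3 of the control or 1 of the treated cells (0.0528, 0.0531 and 0.0624). The cholesterol call ended with the authors' values (0.0558), without background correction (0.0572), with the mean over probes (0.0659), among genes detected on all 12 arrays (0.152) and without control replicate 1 or 3, treated replicate 1 or 2, HCC827-Del control replicate 1 or HCC827-Del treated replicate 3 (0.0509 to 0.0666), and the mesenchymal call ended without a detection filter (0.0735) and with a detection p under 0.05 (0.0522). The endothelial and smooth muscle markers, all 5 undetected in both groups, had 1 member past the threshold (0 adjusted over the list alone, adjusted p = 0.453), and the blood cell markers 3 and 1 of 5 (adjusted p = 0.199).

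**Figure D2:**
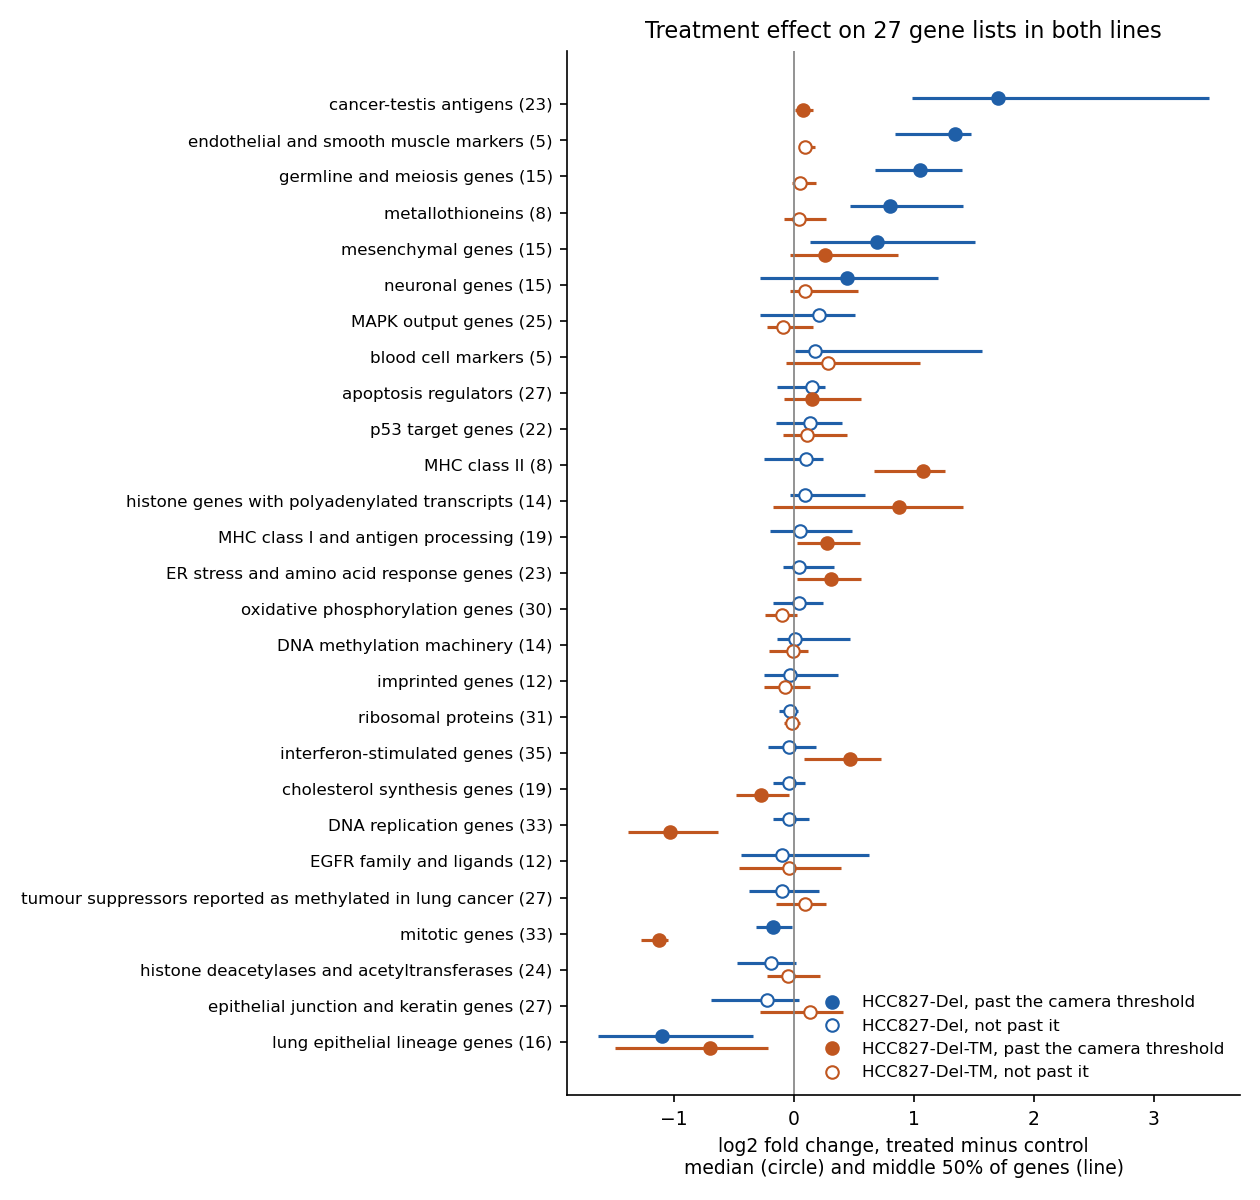
Median log2 fold change of treated over control (circles, x axis) with the range of the middle 50% of genes (lines) for each of 27 gene lists (y axis, number of measured genes in brackets), in HCC827-Del (blue) and HCC827-Del-TM (orange), filled where camera passed the threshold. Cancer-testis antigens lie at 1.70 in HCC827-Del and 0.07 in HCC827-Del-TM, and mitotic genes at -0.18 and -1.12. The antigen medians rest on fitted values: 20 of 23 were undetected in control HCC827-Del, and 18 in both groups of HCC827-Del-TM.

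The third comparison asked how the untreated lines differed. The largest differences were in genes for chemokines, acute-phase proteins and antimicrobial proteins, which were higher in HCC827-Del-TM. The chemokine genes CCL20 and CXCL5 were higher by 5.47 (SE 0.129, adjusted p = 1.22e-12) and 4.64 (SE 0.0798), and the cytokine gene IL1A by 4.41 (SE 0.11). LCN2 (5.08), the fibrinogen chain gene FGG (4.87) and serum amyloid SAA1 (4.18) followed. The other kept probes of SAA1 gave 4.08 (adjusted p = 3.5e-11) and 0.481 (adjusted p = 0.0076). S100A9 and S100A8, which together encode calprotectin, were undetected in HCC827-Del and at least 275-fold and 13.6-fold higher in HCC827-Del-TM. On a list of inflammatory genes drawn up after these values were seen, 24 of 27 measured genes were higher and 1 lower (median 3.23 over the 24 genes with a fold or a bound). Since the genes were chosen from these values, the list is no independent evidence of its direction. CES1, a carboxylesterase gene, and STC1, a secreted glycoprotein gene, were at least 9.48-fold and 6.79-fold higher, PTPN20 at least 14.1-fold and SPDYE1 at least 7.08-fold. The other kept probe of CES1 gave a log2 difference of 0.468 (adjusted p = 0.0023).

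Genes that report signalling through the MAPK pathway were higher in HCC827-Del-TM in 17 of 25 cases and lower in 1 (18 and 1 adjusted over the list alone, median 0.52, adjusted p = 8.22e-10). These included the feedback regulator DUSP6 (1.67) and the early-response gene IER3 (1.37), with CXCL8 at 3.71. Among EGFR family members and ligands, 5 of 12 were higher and 2 lower (adjusted p = 0.662). The ligand genes NRG1 and HBEGF were lower, at -2.32 and -1.78, while EREG was higher by 1.33.

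Interferon-stimulated genes were lower in HCC827-Del-TM, 28 of 35 against 2 higher (29 and 2 adjusted over the list alone, median -0.85, adjusted p = 3.08e-12, and adjusted p = 0.157 with an estimated correlation). IFI27 was at -2.26, IFIT1 at -2.18 and EPSTI1 at -1.90. Of 19 cholesterol synthesis genes, 12 were lower and 1 higher (adjusted p = 0.000189), such as HMGCS1 (-1.18) and LSS (-1.02). Oxidative phosphorylation genes were lower in 13 of 30 cases and higher in 2 (adjusted p = 0.0463, and adjusted p = 0.176 with an estimated correlation), a call that ended with median scaling (0.207), with cyclic loess (0.1), with the mean over probes (0.0509) and without replicate 1, 2 or 3 of control HCC827-Del or 1 or 2 of control HCC827-Del-TM (0.0532 to 0.0725). COX5A was at -0.47, while SDHA went the other way at 1.04.

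DKK3, a secreted Wnt antagonist, was undetected in HCC827-Del-TM and at least 5.47-fold lower, as were the activin antagonist FST (at least 3.8-fold), AMOT (at least 3.91-fold) and PDZK1 (at least 3.95-fold). The caveolin gene CAV1 was at -1.43, and 11 of 27 tumour suppressors were lower and 2 higher (adjusted p = 0.0657), a list that passed without background correction (0.0445), with the authors' values (0.0465), among genes detected on all 12 arrays (0.0373) and without any 1 treated HCC827-Del replicate, control HCC827-Del-TM replicate 1 or treated HCC827-Del-TM replicate 1 or 2 (0.0282 to 0.0479). Other low genes were MAP1LC3C (-2.82), the kallikrein KLK6 (-2.78), DEFB103A (-2.71) and PEG10 (-2.66). CDKN1A was 0.98 higher in HCC827-Del-TM and DNMT1 -0.23 (adjusted p = 0.0283), while UHRF1 gave -0.05 (adjusted p = 0.642). The DNMT1 call ended with median scaling (0.122), with cyclic loess (0.0922), with only the 2 groups compared (0.0572) and without replicate 1 or 3 of control HCC827-Del or 3 of control HCC827-Del-TM (0.0889, 0.0729 and 0.112). In all, 4307 genes differed, 1911 higher and 2396 lower in HCC827-Del-TM, 437 of them by a log2 difference of at least 1, and 4 of 27 lists passed. Cancer-testis antigens (1 of 23 higher and 4 lower, or 1 and 3 adjusted over the list alone) did not pass (adjusted p = 0.842), although MAGEB2 was detected in HCC827-Del-TM alone, at least 3.2-fold higher. The other kept probe of MAGEB2 gave a log2 difference of 0.401 (adjusted p = 0.055).

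The fourth comparison set the treated lines against each other. All 23 cancer-testis antigens were lower in treated HCC827-Del-TM (adjusted p = 1.52e-10), as were 12 of 15 germline genes, against 1 higher (adjusted p = 0.000789, and adjusted p = 0.0628 with an estimated correlation). Without the filter, 23 of 37 antigens (adjusted p = 4e-10) and 16 of 35 germline genes, against 1 higher (adjusted p = 0.000308), were lower. Over the 21 antigens with a fold or a bound, the median was -0.94 with those undetected in treated HCC827-Del-TM at their bound. SPANXC was at -4.05 (SE 0.139) and SPANXD at -3.88 (SE 0.147), CT45A3 was at least 11.4-fold lower, and the antiviral deaminase gene APOBEC3B was at -3.93 (SE 0.105). Proliferation genes were lower as well, with all 33 mitotic genes (median -0.83, adjusted p = 2.36e-10) and 30 of 33 replication genes, 1 being higher (median -1.04, adjusted p = 2.36e-10). CDC20 was at -1.67, CDC45 at -2.00, UHRF1 at -2.15 (SE 0.08) and DNMT1 at -1.04.

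The antimicrobial gene DEFB4A was higher in treated HCC827-Del-TM by 6.18 (SE 0.0972), S100A9 by 5.92 and CCL20 by 4.96. MHC class II genes were higher in treated HCC827-Del-TM in 7 of 8 cases (adjusted p = 0.00141, and adjusted p = 0.0628 with an estimated correlation), MHC class I genes in 12 of 19 with 3 lower (adjusted p = 0.0276, and adjusted p = 0.0644 with an estimated correlation) and epithelial junction and keratin genes in 18 of 27 with 2 lower (adjusted p = 0.00141, and adjusted p = 0.0644 with an estimated correlation). MAPK output genes were higher in 14 of 25 cases and lower in 4 (adjusted p = 0.0228, and adjusted p = 0.0628 with an estimated correlation), and histone genes in 9 and 3 of 14 (adjusted p = 0.0498, and adjusted p = 0.119 with an estimated correlation). BMF and DDIT4, a gene of the stress response, were higher by 3.74 and 2.95. Cholesterol synthesis genes were lower in 13 of 19 cases, with 1 higher (adjusted p = 0.00141), INSIG1 at -2.54. Oxidative phosphorylation genes were lower in 21 of 30, with 1 higher (adjusted p = 0.00394, and adjusted p = 0.0628 with an estimated correlation), which median scaling ended (0.0941). Interferon-stimulated genes were lower in 22 of 35 and higher in 6 (adjusted p = 0.0207, and adjusted p = 0.466 with an estimated correlation), and endothelial and smooth muscle markers in 6 of 13 without the filter (adjusted p = 0.00271), a call lost with an estimated correlation among the filtered genes (adjusted p = 0.0628) and kept without the filter (adjusted p = 0.0414). In all, 7449 genes differed, 3473 higher and 3976 lower, 1453 of them by at least 1, and with median scaling 30.3% were higher in place of 46.6%. Without replicate 1, 2 or 3 of treated HCC827-Del the germline call ended (adjusted p = 0.514, 0.636 and 0.473), for the filter reason given above. Among genes detected on all 12 arrays the germline (0.991), MHC class I (0.061) and histone calls (0.111) ended, and the histone call ended with the replicate block (0.0543) and without any treated HCC827-Del replicate, its control replicate 3, treated HCC827-Del-TM replicate 1 or its control replicate 1 or 2 (0.0521 to 0.0864).

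The last comparison tested directly whether the treatment effect differed between the lines, taking the effect in HCC827-Del-TM minus that in HCC827-Del. Cancer-testis antigens rose more in HCC827-Del, with 22 of 23 differences negative past the threshold and 0 positive (median -1.63, adjusted p = 1.81e-15). The median was -0.57 with the authors' values, and -0.876 over all 37 members without the filter. The fitted differences of VCX3B, VCX and VCX3A were -5.66, -5.52 and -5.20, and those of H2AB1 and TKTL1 were -4.42 and -4.24, fitted values rather than bounds since these genes were undetected in both controls. The other kept probe of VCX3A gave -0.757 (adjusted p = 0.0062). Germline genes gave 11 of 15 negative differences and 1 positive (adjusted p = 0.000183). Without the filter, the antigens gave 23 of 37 negative differences (adjusted p = 1.18e-13) and the germline genes 15 of 35 with 1 positive (adjusted p = 0.000335). Mitotic genes (32 of 33 negative, median -0.95, adjusted p = 1.81e-15) and replication genes (29 of 33 negative and 1 positive, 30 and 1 adjusted over the list alone, median -0.99, adjusted p = 2.87e-14) fell more in HCC827-Del-TM, CDC20 by a difference of -1.27 (SE 0.0937) and CDC45 of -2.10 (SE 0.117). UHRF1 (-2.10, SE 0.113), DNMT1 (-0.82, SE 0.106) and CDKN1A (-0.52, SE 0.112, adjusted p = 0.00191) differed in the same direction.

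Positive differences, toward HCC827-Del-TM, came from S100A8 (3.62, SE 0.137), S100A7 (2.66, SE 0.0918), BMF (2.55, SE 0.138), C6orf58 (2.55) and NFE2 (2.53). BMF rose by 0.87 in HCC827-Del-TM and fell in HCC827-Del. MHC class II genes gave 6 of 8 positive differences (adjusted p = 0.00098, and adjusted p = 0.0576 with an estimated correlation), interferon-stimulated genes 23 of 35 with 3 negative (24 and 3 adjusted over the list alone, adjusted p = 5.97e-05, and adjusted p = 0.239 with an estimated correlation), epithelial junction and keratin genes 12 of 27 with 1 negative (12 and 2 adjusted over the list alone, adjusted p = 0.000406, and adjusted p = 0.0576 with an estimated correlation) and histone genes 9 of 14 with 2 negative (10 and 2 adjusted over the list alone, adjusted p = 0.0114, and adjusted p = 0.0684 with an estimated correlation). KRT7 (1.66) and ELF3 (1.45) led the epithelial list, and NKX2-1, on the lung lineage list, differed by 1.46. Metallothioneins gave 4 of 8 negative differences (adjusted p = 0.00319), with MT1E at -3.02, and endothelial and smooth muscle markers 5 of 13 without the filter (adjusted p = 0.000982). The tumour suppressor list gave 10 positive and 5 negative differences of 27 (adjusted p = 0.13, and 0.0127 among genes detected on all 12 arrays), CDKN2B at 1.45 and IGFBP3 at 1.36. MAPK output genes gave 12 negative and 2 positive differences of 25 (13 and 2 adjusted over the list alone) and did not pass (adjusted p = 0.0546, 0.0929 with an estimated correlation). They passed with 6 other normalizations or filters (0.0192 to 0.0478) and without replicate 3 of control HCC827-Del, 1 or 2 of treated HCC827-Del or 3 of control HCC827-Del-TM (0.0271 to 0.0471).

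Treatment called 2427 genes in the same direction in both lines. Of these, 1206 rose in both, where independent lists of these sizes would share 636.4, and 1221 fell in both, where 754.8 would be shared. Opposite calls numbered 769 against 1386. The log2 fold changes of the lines correlated at r = 0.43 across genes, which are not independent replicates, and the comparisons share no arrays. SPANXC, CDKN1A, SERPINB4 and H1-2 rose in both lines, and SFTPA1, SFTPB and KRT4 fell in both. In all, 5024 genes had a different treatment effect, 2392 positive and 2632 negative, of which 936 differed by at least 1, and 10 of 27 lists passed. With median scaling, 32.2% of the differences were positive in place of 47.6%, and without replicate 1, 2 or 3 of treated HCC827-Del the germline call ended (adjusted p = 0.658, 0.787 and 0.645), as did the metallothionein call without replicate 1 or 3 (0.0833 and 0.0681). Among genes detected on all 12 arrays the germline (0.916), histone (0.0566) and metallothionein calls (0.064) ended.

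With an inter-gene correlation estimated per list, the calls that held were cancer-testis, germline, lung lineage, endothelial and smooth muscle, mesenchymal and metallothionein in HCC827-Del. In HCC827-Del-TM they were mitotic, replication, lung lineage and MHC class II. Between the untreated lines they were MAPK output and cholesterol synthesis, and between the treated lines cancer-testis, mitotic, replication and cholesterol synthesis. For the difference of the treatment effects they were cancer-testis, mitotic, replication, germline, endothelial and smooth muscle, and metallothionein.

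**Figure D3:**
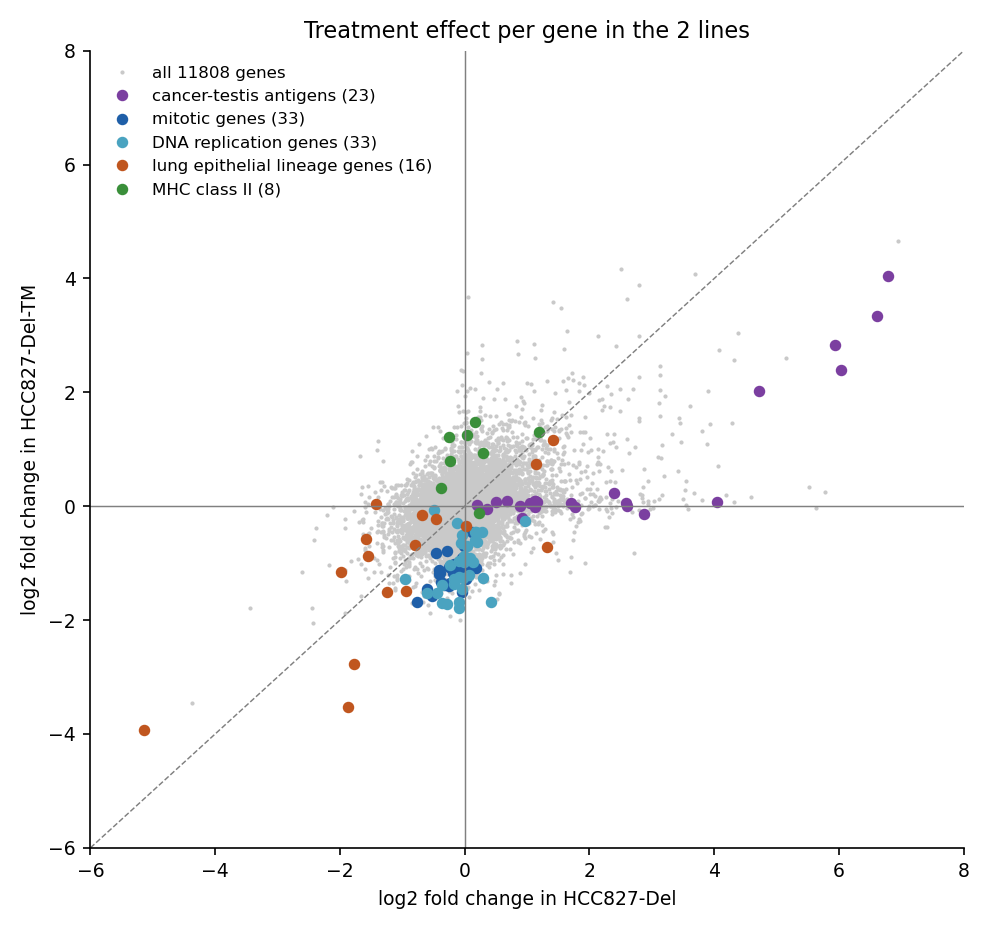
Log2 fold change of treated over control in HCC827-Del (x axis) and HCC827-Del-TM (y axis), 1 point per gene for 11808 genes, with members of 5 lists in colour and equal change as a dashed line. Cancer-testis antigens spread to the right with most near 0 on the y axis, mitotic and replication genes lie below 0 on the y axis, and lung lineage genes lie mostly low on both.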

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

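The tests on CDKN1A and on 1 gene per cancer-testis family, and the inflammatory and myeloid lists, were chosen after the values were seen; the other tests here were set before their results were seen. The treatment effect differed between the lines, by the test of the difference itself (HCC827-Del-TM minus HCC827-Del), for 5024 genes and for 10 lists. The lists with negative median log2 differences were cancer-testis antigens (-1.63), endothelial and smooth muscle markers (-1.24), DNA replication genes (-0.99), mitotic genes (-0.95), germline genes (-0.70) and metallothioneins (-0.44). Those with positive medians were MHC class II (0.86), interferon-stimulated genes (0.57), histone genes (0.43) and epithelial junction and keratin genes (0.37). Medians of lists with undetected members rest on fitted values, and the detection filter kept many cancer-testis, germline and endothelial members through treated HCC827-Del. Without the filter, these 3 lists still passed (medians -0.88, -0.23 and -0.21, adjusted p = 1.18e-13, 0.000335 and 0.000982). Without replicate 1, 2 or 3 of treated HCC827-Del the germline call ended (adjusted p = 0.658, 0.787 and 0.645), as did the metallothionein call without replicate 1 or 3 (0.0833 and 0.0681). Among genes detected on all 12 arrays, the germline (0.916), histone (0.0566) and metallothionein calls (0.064) ended. With an estimated correlation the 4 positive lists did not pass (adjusted p = 0.0576 to 0.239).

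Named genes past the threshold of the same test are given here as fitted log2 differences, which are not bounds where a gene was undetected. SFTPA1 and SFTPB were undetected after treatment in both lines, so their differences follow the levels in the controls. KRT4, FBP1, SLC16A9, CEBPA and H19 were undetected in treated HCC827-Del-TM, so their differences are limited by the detection limit. KRT4 and SLC16A9 fell in both lines, so the positive sign of their differences could come from this limit. The most negative were VCX3B (-5.66), VCX (-5.52), VCX3A (-5.20), H2AB1 (-4.42), TKTL1 (-4.24), CT45A3 (-3.97), SPANXD (-3.64), H19 (-3.54), KRT34 (-3.53), SPANXC (-3.28), SPANXA1 (-3.12) and MT1E (-3.02). Next came STMN3 (-2.86), TUBB2B (-2.82), FAM25A (-2.80), SPANXB1 (-2.75), MAGEB2 (-2.70), COL6A3 (-2.67), KRT13 (-2.60), SBSN (-2.54), SPANXA2 (-2.28), UHRF1 (-2.10), CDC45 (-2.10) and MAEL (-2.02). Then followed FBP1 (-1.92), VWF (-1.78), DEFB103A (-1.76), RRM2 (-1.70), SFTPB (-1.66), EMP3 (-1.59), CD3D (-1.55), HCLS1 (-1.53), FOXM1 (-1.47), INSIG1 (-1.46), BRDT (-1.45) and TYMS (-1.44). Below zero were also DES (-1.39), MCM4 (-1.35), NNAT (-1.32), MYB (-1.31), CDC20 (-1.27), TYROBP (-1.26), PHLDA2 (-1.17), PIWIL2 (-1.09), AURKB (-1.05), SPDEF (-0.99), KIF20A (-0.91) and CEBPA (-0.91). Smaller negative differences were those of CCNA2 (-0.85), DNMT1 (-0.82), MEG3 (-0.80), DNMT3B (-0.64), S100A4 (-0.57), MUC1 (-0.55), CD14 (-0.53), CDKN1A (-0.52) and VGF (-0.52). The most positive were S100A8 (3.62), S100A7 (2.66), BMF (2.55), C6orf58 (2.55), NFE2 (2.53), FCGBP (2.17), CAMP (2.07), PEG10 (2.05), TMEM105 (2.00) and SERPINB3 (1.94). These were followed by HGD (1.83), KRT7 (1.66), SERPINB4 (1.65), SLPI (1.51), HLA-DRA (1.47), NKX2-1 (1.46), ELF3 (1.45), GTF2IRD2B (1.45), CDKN2B (1.45) and IGFBP3 (1.36). Lower positive differences were those of HLA-DRB1 (1.32), EPSTI1 (1.27), CASP1 (1.26), SFTPA1 (1.21), MGMT (1.18), RNASE7 (1.09), VIM (1.08), TCN1 (1.04), KRT4 (0.92) and CASP4 (0.83). The least positive were OAS1 (0.83), CEACAM5 (0.82), CHIA (0.67), H1-2 (0.62), SEMA3B (0.60), SLC16A9 (0.39), DDIT3 (0.39) and H4C8 (0.38). CHIA and CD14 did not pass without background correction (adjusted p = 0.345 and 0.894) or with the authors' values (0.265 and 0.861), nor did CD14 and S100A4 with the mean over probes (0.285 and 0.0762). Another kept probe of HGD (-0.0814, adjusted p = 0.77), MAGEB2 (-0.176, 0.54) and CASP4 (0.0169, 0.95) did not pass. The same held for another kept probe of CD14 (0.219, 0.3), S100A4 (-0.169, 0.44), SEMA3B (0.159, 0.54) and DNMT3B (-0.439, 0.11). The other kept probe of VCX3A passed at a smaller difference (-0.757, 0.0062). Median scaling ended the calls of DDIT3 (0.127), H4C8 (0.355), SEMA3B (0.114) and SLC16A9 (0.121), and cyclic loess that of H4C8 (0.0657). H4C8 and SEMA3B also did not pass without background correction (0.221 and 0.103) or with the authors' values (0.234 and 0.112), and SEMA3B did not without a detection filter (0.0503) or with the mean over probes (0.0851). SEMA3B did not pass either without replicate 1 of control or treated HCC827-Del, 3 of control HCC827-Del-TM or 1 of treated HCC827-Del-TM (0.0691 to 0.075). DDIT3 did not without replicate 1 of treated HCC827-Del, 3 of control HCC827-Del-TM or 1 of treated HCC827-Del-TM (0.05 to 0.0544), H4C8 without replicate 2 of control HCC827-Del or 1 of control HCC827-Del-TM (0.0513 and 0.0501), and SLC16A9 without replicate 1 of control HCC827-Del (0.0506).

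Other splits of the arrays gave these counts. For the genes whose treatment effect differed, 3 of 100 splits drawn from 200 gave at least the real 5024, 1 of them 5068, and 5 more gave 4876 to 4998. All of these kept the treated arrays of each line together, so the count follows the difference between the treated lines. The share of 3 in 100 is under the 0.05 set in advance. These splits, however, cannot tell a difference of treatment effects from a difference between the treated lines. Splits that mix the treated arrays hold the line difference in their spread. The splits thus do not decide on chance for a difference of treatment effects. The highest other split gave 7284: it kept the control arrays in their lines and exchanged the labels of the treated lines, so by construction it measures a structure of the samples, the difference between the lines that control and treated cells share. For the 10 lists, 19 of the 100 gave as many, the highest 14. Every split with more than 10 lists kept the treated arrays of each line together, and so carries the difference between the treated lines. Splits that mixed the treated arrays of the lines reached 10 at most, so chance cannot be excluded for the number of lists. For the 2427 genes changed in the same direction in both lines, 1 of 100 splits, the real one, gave as many and the highest other was 769, which exchanged treated and control arrays in 1 line. Splits that mixed treated and control arrays in a line gave an overlap of 0 in limma, so this count bears on whether each line responded and not on whether the responses are shared. The other 4 comparisons have 10 splits of 6 arrays each, too few for a share under 0.05. In each, 1 of the 10 gave as many genes (6059, 5413, 4307 and 7449 in the order of the report, against 0 in limma in every other split, where 459, 429, 469 and 310 at most had an unadjusted p under 0.05) and as many lists (8, 12, 4 and 13, the highest others 4, 7, 3 and 10). Every other split puts arrays of both groups on each side, so the real difference enters its spread and partly its means. These counts are therefore no chance level, and no conclusion is drawn from them.

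Cancer-testis antigens rose more in HCC827-Del. Sequence shared within a gene family as the source was tested with 1 gene per family. The median difference was -2.34, and 9 of 10 families were lower past the threshold. These genes passed the detection filter, many through treated HCC827-Del, which favours a negative difference, and no family test was run without it. The other kept probe of MAGEB2, 1 of these genes, gave -0.176 (adjusted p = 0.54). Shared sequence therefore stays open. The call of the whole list held in 4 other normalizations (adjusted p at most 1.07e-13). Other scaling between arrays did not shrink the list's median (-1.77 and -1.73). It fell between the bounds of -0.4 and -0.8 set in advance without background correction (-0.58) and with the authors' values, which lack it too (-0.57). How far background correction sets the size stays open. A difference in decitabine uptake or activation is also open: DCK was 0.585 higher (adjusted p = 0.000214) and CDA lower (-0.32, adjusted p = 0.0102, and 0.0502 without control HCC827-Del replicate 1) in untreated HCC827-Del-TM, but the only probe of SLC29A1 was detected on 0 arrays. The difference between the lines that the labels name, the EGFR genotype, stays open and was not tested apart from the lines.

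Mitotic and DNA replication genes fell more in HCC827-Del-TM, with a median of -0.97 over 66 genes. Between-array normalization as the whole cause is argued against by medians of -1.07 to -0.761 over 4 other normalizations, and 1 aberrant array by medians of -0.994 to -0.949 without each array in turn. A larger rise of CDKN1A is argued against by its difference of -0.525, but its level after treatment was 0.46 higher in HCC827-Del-TM, so a higher level is not excluded. A slower cycle in treated HCC827-Del-TM is a hypothesis found and tested on the same data. The cycle itself was not measured, only mRNA. The EGFR genotype and any other difference between the lines stay open, untested.

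Inflammatory genes were higher in untreated HCC827-Del-TM, with a median of 2.89 over 27 genes. RNA from myeloid cells is argued against, since 1 of 27 myeloid genes (CD14, 2.03 higher) was detected and higher there, and TYROBP, FCER1G and SRGN, abundant in myeloid cells, were detected on 0 of its 3 arrays. The cells were a cultured line with no sort in the labels, 6 of the 27 are also on other lists, and 8 were detected on all 3 arrays of both lines. The median stayed at 2.07 to 2.91 over 4 other normalizations. Since the genes were picked for large differences on the same arrays, this test could hardly come out otherwise. It does not decide on normalization. A difference between the lines themselves, such as the EGFR genotype, stays open and untested.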

How the results depend on the processing

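The list tests with 1 gene per cancer-testis family, and the leave-one-out list tests that keep the probes of the full set, were chosen after the values were seen, while the other alternatives were fixed before. Signal over background limits the values most where a gene was undetected: 20 of 23 cancer-testis antigens had no detected probe in control HCC827-Del, so their folds are bounds, and without background correction folds near the background shrink (their median there went from 1.70 to 0.64). The numbers of called genes stayed within 1.5 times under every alternative that kept the thresholds. Median scaling called 75.2% to 83.5% of the same genes in the same direction, and the other 3 normalizations 89.4% to 96.4%, with at most 3 genes in the opposite direction. Median scaling moved the share of called genes that were higher from 48.4% to 61.2% in HCC827-Del, from 46.6% to 30.3% between the treated lines and from 47.6% to 32.2% for the difference of effects. It moved the median of all genes to -0.179 and -0.101 in the last 2. The cause was not tested. The replicate number as a block gave 6021, 5403, 4214, 7437 and 4996 genes. It ended the apoptosis call in HCC827-Del-TM and the histone call between the treated lines, and changed no other list or named gene. Arrays with the same number in different groups correlated at r = -0.0316 to 0.052 after removal of the group means, and 5 of 12 arrays correlated best with their own number. A block for the chip was not run.

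A log2 fold change of at least 1 left 768, 591, 437, 1453 and 936 genes in the order of the report, and an adjusted p under 0.01 left 2866 between the untreated lines, as stricter thresholds do. Among genes detected on all 12 arrays, 0 of 25 lists passed camera in HCC827-Del in place of 8 (6 at an unadjusted p under 0.05, 20 by fry), and 8 in place of 13 between the treated lines. There the germline list turned to -0.177 in HCC827-Del, 0.105 between the treated lines and 0.171 for the difference of effects, since 4 members were left. The estimated correlation kept 4 lists in HCC827-Del-TM, 2 and 4 between the untreated and the treated lines and 6 for the difference of effects (6 in HCC827-Del), and fry called 23, 24, 15, 23 and 23. The first uses the correlation of each list's own genes, and fry compares a list with no other genes. Without background correction and with the authors' values, the difference of CD14 went from -0.53 to 0.0154 and 0.02, and that of CHIA from 0.67 to -0.0893 and -0.10. The cause was not tested.

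Leaving out 1 array gave 5082 to 6065 genes in HCC827-Del, 4802 to 5461 in HCC827-Del-TM, 3669 to 4308 between the untreated lines, 6624 to 7475 between the treated lines and 4325 to 4786 for the difference of effects. The lists numbered 2 to 8, 10 to 12, 3 to 6, 11 to 14 and 7 to 11. With the probes of the full set they numbered 8 to 9, 10 to 12, 3 to 4, 12 to 15 and 10 to 11, so the low counts in HCC827-Del come from the filter: without 1 array of treated HCC827-Del, 5 to 6 of 23 cancer-testis antigens and 6 of 15 germline genes were still tested. The genes called in both lines in the same direction numbered 2191 to 2294, and r was 0.426 to 0.457.

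Of 155 list values per alternative, those that lost the threshold numbered 2 with median scaling, 1 each with cyclic loess, no background correction, the authors' values and no detection filter, 18 of 145 among genes detected on all 12 arrays, and 2 each with a detection p under 0.05, the mean over probes and the block. None did with trend and robust variances or array weights, and 42 of 1845 did when 1 array was left out. Lists newly passed too: 6 with median scaling, 5 with cyclic loess, 7 each with no background correction and the authors' values, 8 without a detection filter, 4 among genes detected on all 12 arrays, 2 with a detection p under 0.05 and 21 of 1845 with 1 array left out. Beside the lists named with such gains elsewhere in the text, these were epithelial junction genes for treatment in both lines, oxidative phosphorylation genes for treatment in HCC827-Del-TM and the difference of effects, MHC class I genes for the difference of effects, ER stress genes between the treated lines, and apoptosis regulators between the untreated and the treated lines. Of 277 named values, those that lost it numbered 5 with median scaling, 2 with cyclic loess, 4 each with no background correction and the authors' values, 1 without a detection filter, 3 with the mean over probes, 1 of 182 with only the 2 groups and 14 of 3231 with 1 array left out. Those that newly passed came from EGFR with the mean over probes.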

Other observations

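The gene lists of squamous, myeloid, inflammatory and decitabine uptake genes, and KRT13, KRT34, SLPI, HCLS1, TYROBP and LCP1 among the genes named here, were chosen after the values were seen, so the p-values of these lists are descriptive. Genes on the squamous and barrier list rose on balance with treatment in both lines, although KRT4, the keratin of stratified epithelium named above, fell in both. In HCC827-Del, 12 of 16 measured members rose and 2 fell (camera adjusted p = 3.69e-05, and adjusted p = 0.00573 with an estimated correlation). The keratin genes KRT34 and KRT13 led, KRT34 by 3.55 (SE 0.0982) and KRT13 at least 4.62-fold from undetected. In HCC827-Del-TM, 7 rose and 3 fell (adjusted p = 0.00411, and adjusted p = 0.0213 with an estimated correlation), with the protease inhibitor gene SLPI at 1.38 (SE 0.0977). KRT34 gave 0.02 there (adjusted p = 0.883) and differed between the lines by -3.53, KRT13 by -2.60 and SLPI by 1.51. The list did not separate the treatment effects of the lines, with 7 positive and 7 negative differences (7 and 8 adjusted over the list alone, adjusted p = 0.682). Among genes detected on all 12 arrays, the squamous call ended in HCC827-Del (adjusted p = 0.471) and in HCC827-Del-TM (adjusted p = 0.267).

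Genes of myeloid cells rose as well. Of 18 measured members, 9 rose and 4 fell in HCC827-Del (10 and 4 adjusted over the list alone, adjusted p = 0.00799, and adjusted p = 0.0356 with an estimated correlation), and 11 rose and 2 fell in HCC827-Del-TM (11 and 3, adjusted p = 0.00651, and adjusted p = 0.0213). Among genes detected on all 12 arrays, the myeloid call ended in both lines (adjusted p = 0.43 and 0.259). The signalling adaptors HCLS1 and TYROBP rose at least 2.73-fold and 2.52-fold from undetected in HCC827-Del, and the receptor gene CD14 rose by 1.57 (SE 0.101) in HCC827-Del and 1.05 in HCC827-Del-TM. LCP1, an actin-bundling gene, rose by 0.51 and 0.52. Inflammatory genes, already higher in untreated HCC827-Del-TM, rose further, 15 of 27 against 3 that fell (adjusted p = 1.21e-06, and adjusted p = 0.0213 with an estimated correlation). In HCC827-Del 13 rose and 4 fell (14 and 4 adjusted over the list alone, adjusted p = 0.00126, and adjusted p = 0.08 with an estimated correlation). The difference of the treatment effects did not pass for the inflammatory list (adjusted p = 0.646, but 0.0423 without background correction and 0.0448 with the authors' values) or the myeloid list (adjusted p = 0.646).

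Imprinted genes, expressed from 1 parental copy, did not move together. Of 12 measured, 3 rose and 1 fell in HCC827-Del (adjusted p = 0.758), and 1 rose and 2 fell in HCC827-Del-TM (adjusted p = 0.688). The non-coding H19 rose by 2.71 (SE 0.109) in HCC827-Del and was lost, at least 1.11-fold, in HCC827-Del-TM. NNAT and MEG3 rose at least 1.42-fold and 1.24-fold in HCC827-Del, and PHLDA2 fell by 0.94 in HCC827-Del-TM. Ribosomal protein genes gave 0 rises and 6 falls of 31 in HCC827-Del (0 and 5 adjusted over the list alone, adjusted p = 0.497) and 0 and 4 in HCC827-Del-TM (0 and 0, adjusted p = 0.765). With median scaling, the ribosomal list passed in HCC827-Del (median -0.13, adjusted p = 0.00534), between the treated lines (0.04, adjusted p = 0.0455) and for the difference of effects (0.13, adjusted p = 0.0148). Genes for the uptake and activation of decitabine had 1 of 7 higher and 4 lower in HCC827-Del (2 and 4 adjusted over the list alone, adjusted p = 0.221) and 1 and 4 in HCC827-Del-TM (adjusted p = 0.149).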
